A study of Homo sapiens with 40 samples.

How the data were processed

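RNA was measured in 40 libraries from HEK293T cells of 5 lines, with 4 libraries per line and treatment (vehicle, or antimycin A at 40 nM, both over 6 hours). Per the submitters' protocols, poly(A) RNA was enriched, primed with random hexamers and read as 150-base pairs on a T7 instrument. The deposited table gives raw counts per gene symbol and library, without normalization. Per the submitters' processing notes, HISAT2 2.1.0 and featureCounts 2.0.6 were used with hg38. Their settings, the annotation and the strandedness are not given in the sources used here. The table has 28278 gene symbols. It holds 0 of the 13 genes encoded in mitochondrial DNA, which are therefore not analysed here. Each library was assigned to its group by the library name in its label.

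Library totals ran from 30.7 to 32.0 in units of 1e6 counts. Among counts from 1 to 20, between 55.1% and 58.7% per library were even. The variance of low counts between libraries of a group was 1.93 to 2.02 times the Poisson value. Counting some read pairs 2 times could raise both values. Not every pair can have counted 2 times, since low counts would then nearly all be even. The cause was not tested. The common biological coefficient of variation was 0.0509.

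Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and statmod 1.5.0. Counts were filtered with filterByExpr, which left 16739 genes, scaled by TMM and fitted by edgeR's robust quasi-likelihood model with 1 coefficient per group. Each comparison was a contrast of this fit, including the differences of the antimycin response between lines. Benjamini-Hochberg adjustment ran over all tested genes of a contrast, with a call at an adjusted p < 0.05. CPM values use each library's total over the tested genes, scaled by TMM, and log2 CPM values add a prior count of 2. In total 20 comparisons were fixed before the data were examined. Comparisons of the libraries labelled KO plus SLC25A12-WT and of F137S cells with WT-vector cells were added afterwards.

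Gene lists written before the data were examined numbered 29, of which 28 had at least 3 tested members. Each list was tested with camera at an inter-gene correlation of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list moved more than other genes. A list's members were also counted as called, with adjustment over all genes and over the list alone. The ISR list of 35 ATF4 target genes also gave a level per library, the mean log2 CPM of its members, tested by exact permutation of libraries between groups. For 4 against 4 libraries there are 35 splits and the smallest p is 0.0286. Differences of response have 4900 arrangements and a smallest p of 0.000408.

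The genes named follow a rule fixed before the data were examined. It takes genes with a symbol other than a clone, LOC or LINC name, a mean log2 CPM of at least 1, an adjusted p < 0.05 and, for pairs of groups, no overlap between libraries. From these it takes the 8 largest log2 fold changes each way for the antimycin responses of WT-vector and KO-vector cells and for these lines in vehicle, and 4 each way elsewhere. Added are up to 4 members of each list, ATF4, DDIT3, ATF3, TRIB3, ASNS and GDF15 for antimycin responses, and SLC25A12, SLC25A13, DELE1, EIF2AK1 and OMA1. The text may name fewer. The HOXA genes were named after their values were seen.

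Alternatives fixed before the data were examined were DESeq2 size factors, no filter, the DESeq2 Wald test, a fit of the compared groups alone, the replicate number as a block, a call at 2-fold or more, each library left out in turn, a prior count of 0.5, the ISR list without members of other lists, and the estimated correlation. Added afterwards were counts halved, a fit without the libraries labelled KO plus SLC25A12-WT, line means removed before permutation, and lists without the short arm of chromosome 19. The main tests are unpaired, since residuals of libraries with the same replicate number correlated at -0.00137 on average over genes. Single pairs of libraries ranged from -0.245 to 0.227. The average therefore does not exclude pairing for a single measure such as the ISR level, which was also tested with the replicate block.

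The procedure was tested on simulated data for 16304 genes, with the means of WT-vector cells in vehicle and 1 fixed spread for every gene. Changes were put into the WT-vector antimycin libraries. Far fewer genes were changed than were called in the data, so the rates below need not hold there. Of 50 genes changed at each size, 12 were recovered at 1.1-fold, 40 at 1.25-fold, 47 at 1.5-fold and 47 at 2-fold, with 9 false calls (5.81% of calls). Of 28 random lists, 0 passed a camera p of 0.05. The simulated genes were independent of each other, so this does not test lists of correlated genes.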

Results

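SLC25A12 mRNA, the transcript of the mitochondrial aspartate and glutamate carrier that was knocked out, was measured together with 16739 tested genes in HEK293T cells of 5 lines. Each line received vehicle or 40 nM antimycin A, an inhibitor of respiratory complex III, for 6 hours, with 4 libraries per group and 40 in all. The labels call these libraries biological replicates and do not say whether they are separate cultures. The lines are wild-type cells with vector (WT vector), knockout cells with vector (KO vector), and cells labelled as knockout plus SLC25A12-WT, knockout plus SLC25A12-F137S, or knockout plus SLC25A12-F137S and dMTS-DELE1. The last 2 are called F137S cells and dMTS-DELE1 cells here. Log2 fold changes are given ± a standard error derived from the test statistic of the fit over all 40 libraries, with n = 4 per group. Such values stand in brackets after a gene, with the adjusted p for chosen genes and for those that did not pass. A gene rose, fell or changed where its edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p < 0.05.

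In vehicle, SLC25A12 stood at 38.7 ± 1.82 CPM (mean ± SD) in WT-vector cells and 3.08 ± 0.231 in KO-vector cells. It reached 1853 ± 18.3 in F137S cells and 3716 ± 25.7 in dMTS-DELE1 cells, far above the native level. The libraries labelled KO plus SLC25A12-WT held 38.9 ± 0.330 CPM, the level of WT-vector cells and not that of an overexpressed transgene. DELE1, which encodes a mitochondrial protein that relays stress to the kinase HRI, stood at 45.9 ± 2.15 CPM in F137S cells and at 5344 ± 84.7 in dMTS-DELE1 cells. Under antimycin SLC25A12 stood at 30.6 CPM in WT-vector, 2.75 in KO-vector, 29.9 in labelled, 1908 in F137S and 4272 in dMTS-DELE1 cells. Antimycin lowered it in WT-vector cells (log2 fold change -0.34 ± 0.03, adjusted p = 1.0e-15) and by about as much in the libraries labelled KO plus SLC25A12-WT (-0.38 ± 0.03, adjusted p = 9.9e-18). In F137S cells it did not pass (0.04 ± 0.02, adjusted p = 0.051), and in dMTS-DELE1 cells it rose (0.20 ± 0.02, adjusted p = 1.4e-14).

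**Figure D1:**
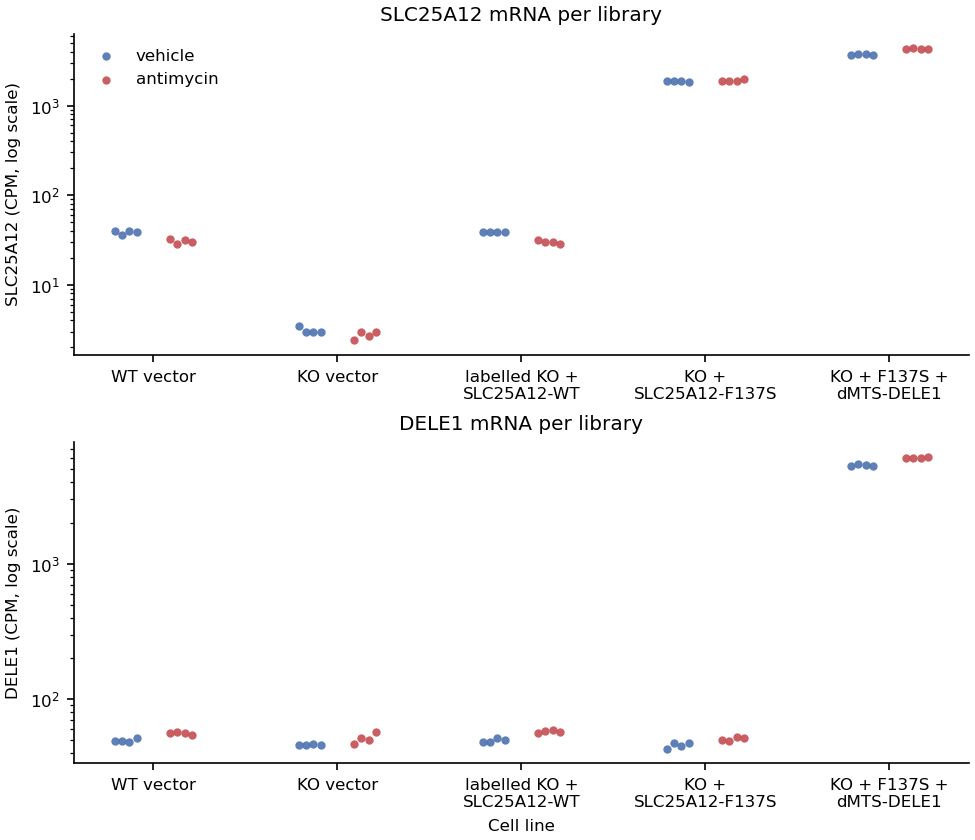
SLC25A12 (top) and DELE1 (bottom) mRNA in CPM on a log scale, 1 point per library, by cell line, with vehicle in blue and antimycin in red.

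In WT-vector cells, antimycin raised the genes of the integrated stress response (ISR), the program run by the transcription factor ATF4. CHAC1, which degrades glutathione, rose most among the genes named for this comparison (3.17 ± 0.12, adjusted p = 4.1e-30). ATF3, a stress-induced transcription factor (1.58 ± 0.04), ASNS, which makes asparagine (1.47 ± 0.14), and NUPR1, a small stress protein (1.96 ± 0.16), rose as well. So did DDIT3, which encodes CHOP (0.86 ± 0.07), GDF15, a secreted stress hormone with few counts here (1.72 ± 0.40), and, by less, ATF4 itself (0.35 ± 0.02, adjusted p = 1.2e-29) and TRIB3 (0.32 ± 0.05). Of the 35 genes of the ISR list, 29 rose, 4 fell and 2 did not pass, with 29 up and 5 down adjusted over the list alone, a median of 0.67 and camera adjusted p = 3.0e-14. The mean log2 level of the list rose from 4.11 ± 0.0347 (mean ± SD) to 4.75 ± 0.0215 per library, a difference of 0.63 (exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give).

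Amino acid transporters and genes of serine, one-carbon and proline metabolism leaned upward with the ISR in WT-vector cells. Of 20 amino acid transporters, 13 rose and 5 fell (14 up and 6 down adjusted over the list alone). The glycine transporter SLC6A9 led them (1.43 ± 0.06) with SLC43A1 (0.77 ± 0.05) and SLC7A3 (0.73 ± 0.08). Of 23 genes of serine, one-carbon and proline metabolism, 11 rose and 7 fell (13 up and 7 down adjusted over the list alone). Among them are PCK2, mitochondrial phosphoenolpyruvate carboxykinase (1.21 ± 0.05), PSAT1 (0.48 ± 0.02), AMT (0.62 ± 0.10) and, downward, SLC25A32 (-0.49 ± 0.03). Camera gave adjusted p = 0.00038 for the transporters and 0.0065 for the serine list. Cytosolic tRNA synthetases were 12 up and 5 down of 20 (12 up and 5 down adjusted over the list alone). AARS1 stood at 0.45 ± 0.02 and GARS1 at 0.24 ± 0.02. Their camera call (camera adjusted p = 0.02) was lost (adjusted p = 0.2 with an estimated correlation).

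Proliferation genes mostly fell under antimycin in WT-vector cells, while p53 target genes leaned upward. Cell cycle arrest and p53 activity were not measured. Of 35 cell cycle genes, 21 fell and 7 rose (7 up and 21 down adjusted over the list alone, camera adjusted p = 1.1e-04). The mitotic kinases AURKA (-0.75 ± 0.03) and PLK1 (-0.60 ± 0.04) fell and E2F1 rose (0.63 ± 0.04). Of 20 p53 target genes, 10 rose and 2 fell (10 up and 2 down adjusted over the list alone, camera adjusted p = 0.018). They include BBC3 (0.73 ± 0.09), BTG2 (0.70 ± 0.05) and the cell cycle inhibitor CDKN1A (0.65 ± 0.07). Immediate early genes were 11 up and 2 down of 23 (12 up and 2 down adjusted over the list alone, camera adjusted p = 0.004). JUN (1.27 ± 0.03) and CCN1 (0.99 ± 0.06) rose and MYC (-0.81 ± 0.04) and EGR2 (-1.06 ± 0.45, few counts) fell. Chaperone genes of the heat shock list were 14 down and 2 up of 19 (2 up and 14 down adjusted over the list alone). Among them are HSPA1B (-0.58 ± 0.08), HSPA1A (-0.56 ± 0.09) and HSPA8 (-0.47 ± 0.03). The heat shock call (camera adjusted p = 2.2e-04) was lost (adjusted p = 0.07 with an estimated correlation). Mitochondrial ribosomal protein genes were 31 down and 6 up of 74 (6 up and 31 down adjusted over the list alone, camera adjusted p = 0.014, but adjusted p = 0.41 with an estimated correlation). The endoplasmic reticulum stress list of ATF6 and XBP1 targets had no common direction in WT-vector cells (5 up, 11 down of 24, 5 up and 11 down adjusted over the list alone, camera adjusted p = 0.36). DNAJB9 (-0.49 ± 0.05), SEL1L (-0.25 ± 0.03) and SDF2L1 (-0.25 ± 0.04) fell.

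Among the strongest changes in WT-vector cells were also ULBP1, a ligand of a natural killer cell receptor (1.88 ± 0.11), GUCA1B (1.77 ± 0.15) and ZNNT1 (1.71 ± 0.14), all up. GNG13, a G protein subunit (-1.53 ± 0.11), fell, as did the small nucleolar RNAs SNORA73B (-1.87 ± 0.15), SNORA73A (-1.53 ± 0.12), SNORD78 (-1.67 ± 0.16) and SNORD101 (-1.40 ± 0.17), whose capture in poly(A) libraries is partial. ASNSP1, a pseudogene that shares sequence with ASNS, rose with it. CIRBP-AS1 (-1.42 ± 0.13) is an antisense RNA, and strandedness is not given in the sources used here. RPS9 (1.75 ± 0.67, adjusted p = 0.028), NTAN1 (2.39 ± 0.75, adjusted p = 0.0078) and SNHG32 (-2.02 ± 0.69, adjusted p = 0.015) had large errors, their counts varying widely between libraries of a group. In all, 8680 of 16739 genes (51.9%) changed, 4265 up and 4415 down, 595 of them by at least 2-fold. Of the known parts of the mitochondrial relay to ATF4, DELE1 (0.18 ± 0.04) and EIF2AK1, which encodes HRI (0.15 ± 0.02), rose slightly, OMA1 did not pass (-0.06 ± 0.04, adjusted p = 0.28), and SLC25A13, the paralog of SLC25A12, fell (-0.29 ± 0.03).

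KO-vector cells also raised ISR genes under antimycin, but by less. CHAC1 (1.91 ± 0.12, adjusted p = 8.0e-20), ATF3 (1.36 ± 0.04), ASNS (0.95 ± 0.15), NUPR1 (1.11 ± 0.19) and DDIT3 (0.63 ± 0.07) rose, and ATF4 rose by little (0.07 ± 0.02, adjusted p = 4.4e-04). TRIB3 did not pass (0.08 ± 0.05, adjusted p = 0.18), and GDF15, with 2 counts in the 4 vehicle libraries and 10 in the 4 antimycin libraries, is too scarce for a fold change. Of the 35 ISR genes, 22 rose, 3 fell and 10 did not pass, with 23 up and 3 down adjusted over the list alone, a median of 0.18 and camera adjusted p = 3.0e-05. SLC7A11, the cystine transporter and an ISR gene, fell (-0.56 ± 0.03). PCK2 (0.80 ± 0.05), SLC6A9 (0.72 ± 0.06), AMT (0.59 ± 0.10) and AARS1 (0.31 ± 0.02) rose. The mean log2 level of the ISR list rose by 0.38, from 4.01 ± 0.0518 to 4.39 ± 0.0464 (exact permutation p = 0.0286).

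The rest of the antimycin response in KO-vector cells resembled that of WT-vector cells. The changes of 12752 genes correlated at r = 0.867 between the 2 lines, although genes are not independent replicates, and 6873 genes changed in the same direction in both against 22 in opposite directions. Of 35 cell cycle genes, 23 fell and 7 rose (7 up and 24 down adjusted over the list alone, camera adjusted p = 1.5e-04). The p53 targets were 10 up and 2 down of 20 (11 up and 2 down adjusted over the list alone, camera adjusted p = 0.018), with BTG2 at 0.74 ± 0.05. JUN rose (1.02 ± 0.03), JUND rose (1.33 ± 0.10) and MYC fell (-0.98 ± 0.04) within an immediate early list of 9 up and 1 down (9 up and 1 down adjusted over the list alone, camera adjusted p = 0.014, but adjusted p = 0.062 with an estimated correlation). Genes of the endoplasmic reticulum list leaned upward, 11 up and 3 down of 24 (11 up and 3 down adjusted over the list alone). Examples are MANF (0.30 ± 0.04), PDIA4 (0.29 ± 0.02), CRELD2 (0.26 ± 0.04) and HERPUD1 (0.24 ± 0.03). The call (camera adjusted p = 0.017) was lost at adjusted p = 0.18 with an estimated correlation. Nuclear genes of complex I (18 up, 0 down of 37, 18 up and 0 down adjusted over the list alone) and of complexes II to V (24 up, 2 down of 36, 24 up and 2 down adjusted over the list alone) also leaned upward. Their camera calls (adjusted p = 0.017 and 0.0070) were lost at adjusted p = 0.45 and 0.43 with an estimated correlation. Heat shock genes were 11 down and 2 up of 19 (3 up and 11 down adjusted over the list alone, camera adjusted p = 0.016, but adjusted p = 0.25 with an estimated correlation), with HSPA1A at -0.49 ± 0.10 and HSPA1B at -0.44 ± 0.08.

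Other strong changes in KO-vector cells were ZNNT1 (2.06 ± 0.14), LFNG, a modifier of Notch (1.46 ± 0.15), TLCD1 (1.40 ± 0.07), SERTAD1 (1.36 ± 0.09) and TENT5C (1.35 ± 0.07), all up. The vitamin D hydroxylase CYP27B1 (-1.60 ± 0.08), GNG13 (-1.69 ± 0.11), LNP1 (-1.47 ± 0.11), BNC2 (-1.47 ± 0.16), the small nucleolar RNAs SNORA73B (-1.70 ± 0.14) and SNORD78 (-1.46 ± 0.16) and the pseudogene TPI1P2 (-1.43 ± 0.19) fell. DELE1 (0.16 ± 0.04) and EIF2AK1 (0.08 ± 0.02) rose slightly, SLC25A13 fell (-0.20 ± 0.03) and OMA1 did not pass (0.03 ± 0.04, adjusted p = 0.55). The count was 8541 genes (51.0%), 4412 up and 4129 down, 483 of them by at least 2-fold.

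The direct test of the difference between the 2 antimycin responses found ISR genes among those that differed. For SLC25A12 itself the difference did not pass (0.17 ± 0.09, adjusted p = 0.58). CHAC1 (-1.26 ± 0.18, adjusted p = 2.3e-06), ADM2 (-0.97 ± 0.24, adjusted p = 0.016), JDP2 (-0.59 ± 0.13, adjusted p = 0.0049), CTH, which makes cysteine (-0.52 ± 0.06), ATF4 (-0.28 ± 0.02, adjusted p = 2.0e-14) and ATF3 (-0.22 ± 0.06, adjusted p = 0.036), which antimycin raised in WT-vector cells, had a more negative response in KO-vector cells. SLC7A11, which fell in both lines, fell further in KO-vector cells (-0.48 ± 0.05). Differences of response are signed here, so a more negative response is a smaller rise or a larger fall. Of 35 ISR genes, 15 had a more negative response, 0 a more positive one and 20 did not pass, with 1 up and 24 down adjusted over the list alone, a median difference of -0.23 and camera adjusted p = 2.2e-29. TRIB3 (-0.24 ± 0.07, adjusted p = 0.057), DDIT3 (-0.23 ± 0.09, adjusted p = 0.28) and ASNS (-0.52 ± 0.20, adjusted p = 0.23) did not pass, nor did GDF15 with its few counts. The mean log2 level of the list rose by 0.26 less in KO-vector cells. The planned permutation of line labels within each treatment gave p = 0.0633, which counts the standing difference between the lines as noise. With the line means removed first, a permutation chosen after seeing the data, p = 0.000408, the smallest that its arrangements can give.

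Amino acid supply genes followed the ISR in this difference, and endoplasmic reticulum genes went the other way. Of 20 amino acid transporters, 9 had a more negative and 1 a more positive response (2 up and 10 down adjusted over the list alone, camera adjusted p = 5.1e-11), with SLC6A9 at -0.71 ± 0.09. Of 23 serine and one-carbon genes, 7 were more negative and 0 more positive (2 up and 8 down adjusted over the list alone, camera adjusted p = 3.0e-07), with PCK2 (-0.41 ± 0.07), PSPH (-0.33 ± 0.05) and PSAT1 (-0.29 ± 0.03). Of 20 tRNA synthetases, 7 were more negative and 0 more positive (0 up and 10 down adjusted over the list alone, camera adjusted p = 1.3e-12), with GARS1 (-0.19 ± 0.03) and SARS1 (-0.17 ± 0.03). Of 24 endoplasmic reticulum stress genes, 10 had a more positive response in KO-vector cells and 0 a more negative one (17 up and 0 down adjusted over the list alone, camera adjusted p = 4.2e-19). Among them are DNAJB9 (0.45 ± 0.07) and SDF2L1 (0.34 ± 0.06), which fell in WT-vector cells and did not pass in KO-vector cells, and HERPUD1 (0.30 ± 0.04) and MANF (0.26 ± 0.05). Heat shock genes, which mostly fell in both lines, also leaned to a more positive response (3 more positive, 0 more negative of 19, 6 up and 0 down adjusted over the list alone, camera adjusted p = 4.6e-05), a call lost at adjusted p = 0.085 with an estimated correlation.

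Beyond the lists, the collagen receptor DDR2 (-1.26 ± 0.10) and CRIP2 (-1.09 ± 0.20) had a more negative response in KO-vector cells, with the pseudogene ASNSP1 (-1.02 ± 0.24). RGS20 (0.80 ± 0.21, adjusted p = 0.022), SHISA4 (0.78 ± 0.22, adjusted p = 0.047), the pseudogene TEKT4P2 (0.67 ± 0.18, adjusted p = 0.028) and SLC39A7, a zinc transporter whose counts vary between libraries of a group (1.33 ± 0.32, adjusted p = 0.026), had a more positive one. In all 262 genes differed in response, 140 more positive and 122 more negative in KO-vector cells, 15 of them by at least 2-fold. With DESeq2 size factors in place of TMM scaling, the share with a more positive response was 42.2% in place of 53.4%.

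**Figure D2:**
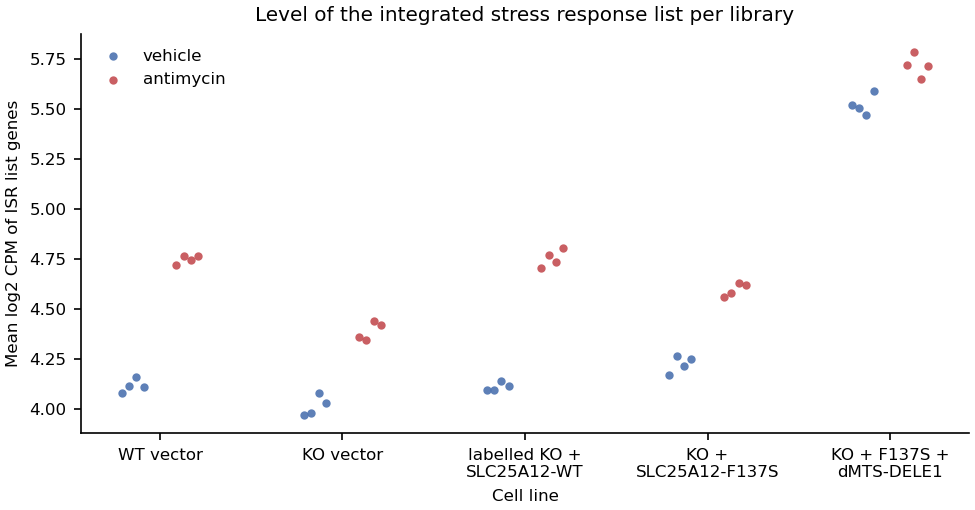
Mean log2 CPM of the 35 ISR genes, 1 point per library, by cell line, with vehicle in blue and antimycin in red.

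**Figure D3:**
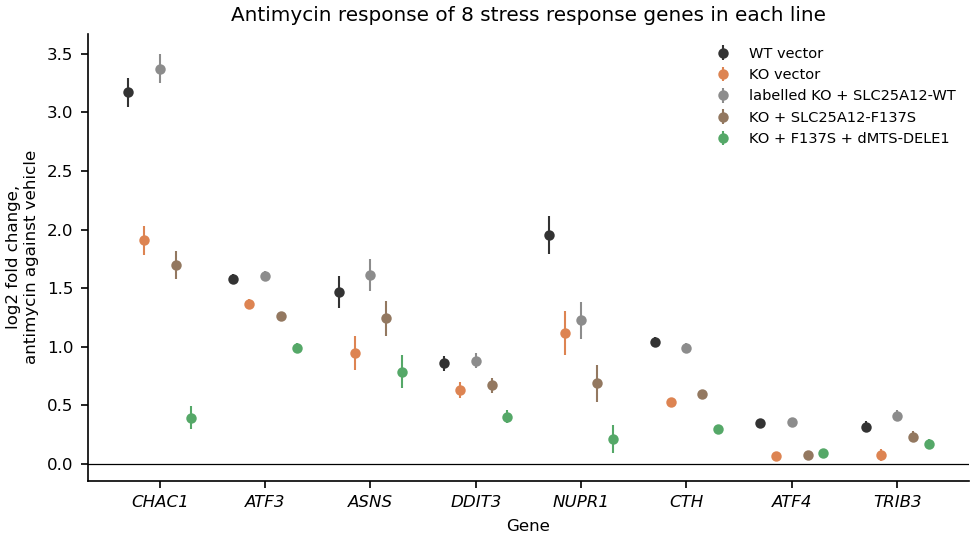
Log2 fold change under antimycin of 8 ISR genes in each of the 5 lines, with standard errors derived from the test statistic of the fit (n = 4 per group). All 8 rose in WT-vector cells, and the members of the ISR list that fell there are not shown.

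In vehicle, KO-vector cells differed from WT-vector cells across much of the transcriptome. SLC25A12 was 12.5-fold lower (log2 fold change -3.65 ± 0.05, adjusted p = 3.7e-64). HAS2, a hyaluronan synthase (-4.75 ± 0.21), the apoptosis protease CASP8 (-2.83 ± 0.08), AGAP11 (-2.68 ± 0.14), DDR2 (-2.58 ± 0.07), DHRS2 (-2.25 ± 0.11) and TENM1 (-2.21 ± 0.04) were lower. The neuronal kinesin KIF1A (2.28 ± 0.04), the imprinted gene MKRN3 (2.50 ± 0.13), TPTE (2.43 ± 0.12), IGFBP7 (1.66 ± 0.13), FAM133A (1.71 ± 0.11), TRIM58 (1.62 ± 0.11) and the pseudogene DBIL5P (6.76 ± 0.06) were higher. NAPRT (-2.27 ± 0.48) was lower with counts that vary between libraries of a group. SLC25A13 (-0.19 ± 0.03), OMA1 (-0.38 ± 0.04) and DELE1 (-0.11 ± 0.04) were slightly lower, and EIF2AK1 did not pass (-0.01 ± 0.02, adjusted p = 0.73).

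Endoplasmic reticulum stress genes and mitochondrial chaperones and proteases were lower in KO-vector cells. Of 24 genes of the ATF6 and XBP1 list, 19 were lower and 0 higher (0 up and 20 down adjusted over the list alone, median -0.26, camera adjusted p = 1.2e-14). Among them are HERPUD1 (-0.99 ± 0.03), SDF2L1 (-0.92 ± 0.04), DNAJB9 (-0.71 ± 0.05) and the chaperone CALR (-0.65 ± 0.02). Of 20 mitochondrial chaperones and proteases, 15 were lower and 0 higher (0 up and 15 down adjusted over the list alone, camera adjusted p = 4.1e-05). Among them are CLPP (-0.70 ± 0.04), LONP1 (-0.56 ± 0.03) and TRAP1 (-0.33 ± 0.02). The ISR list had no common direction (10 higher, 13 lower of 35, 11 up and 14 down adjusted over the list alone, camera adjusted p = 0.92). NDRG1 was lower (-0.97 ± 0.04) and NIBAN1 (0.65 ± 0.07) and SLC7A11 (0.60 ± 0.03) higher. GDF15 passed with 2 counts in the 4 KO-vector libraries against 20 in the 4 WT-vector libraries, too few for a fold change. The mean log2 level of the ISR list differed by -0.10 (exact permutation p = 0.0571).

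Several lists leaned lower in KO-vector cells without a call that holds under the correlation estimated from the data. Of 78 cytosolic ribosomal protein genes, 52 were lower and 5 higher (5 up and 54 down adjusted over the list alone, camera adjusted p = 4.1e-09, but adjusted p = 0.34 with an estimated correlation), with RPS28 at -0.57 ± 0.08. Mitochondrial ribosomal protein genes were 40 lower and 8 higher of 74 (8 up and 41 down adjusted over the list alone, camera adjusted p = 9.8e-04, but adjusted p = 0.2 with an estimated correlation), with MRPL54 (-0.86 ± 0.07) and MRPL4 (-0.78 ± 0.04). Immediate early genes were 14 lower and 2 higher of 23 (2 up and 14 down adjusted over the list alone, camera adjusted p = 0.0097, but adjusted p = 0.082 with an estimated correlation), with DUSP5 (-1.19 ± 0.12), EGR1 (-1.06 ± 0.17), ARC (-1.09 ± 0.21) and EGR3 (-1.16 ± 0.34). tRNA synthetases were 14 lower and 3 higher of 20 (3 up and 14 down adjusted over the list alone, camera adjusted p = 0.0037, but adjusted p = 0.1 with an estimated correlation). Nuclear complex I genes were 15 lower and 4 higher of 37 (4 up and 15 down adjusted over the list alone, camera adjusted p = 0.045, but adjusted p = 0.6 with an estimated correlation), with NDUFA7 (-0.70 ± 0.06) and NDUFB7 (-0.62 ± 0.05). Among sterol genes, INSIG1 (-0.75 ± 0.03) was lower, though the cholesterol list had no common direction (camera adjusted p = 0.92). The count was 8080 genes (48.3%), 3803 higher and 4277 lower, 572 of them by at least 2-fold.

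Genes of the short arm of chromosome 19 were lower as a block in KO-vector cells. Of 388 such genes, 358 (92.3%) had a negative log2 fold change and 333 were called lower, with a median of -0.51, while the median over 458 genes of the long arm was 0.02. No other run of as many neighbouring genes was as low, in 11646 windows elsewhere, the lowest of which had a median of -0.19. CLPP, LONP1, CALR, NDUFA7, NDUFB7, MRPL54, MRPL4 and RPS28 lie on this arm. In vehicle the arm was also low in F137S cells (mean of 4 libraries -0.512 relative to other genes) and in dMTS-DELE1 cells (-0.560), against -0.502 in KO-vector cells and -0.00972 in the libraries labelled KO plus SLC25A12-WT. Without the genes of this arm, the complex I list lost its call (adjusted p = 0.226) and the endoplasmic reticulum and mitochondrial chaperone lists kept theirs (adjusted p = 1.5e-14 and 4.7e-04). The ISR difference under antimycin is not made up of genes on this arm, which holds 1 of the 35, GDF15. Whether the fall of the arm alters ISR genes located elsewhere was not tested. The search over chromosome arms was chosen after seeing the data.

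**Figure D4:**
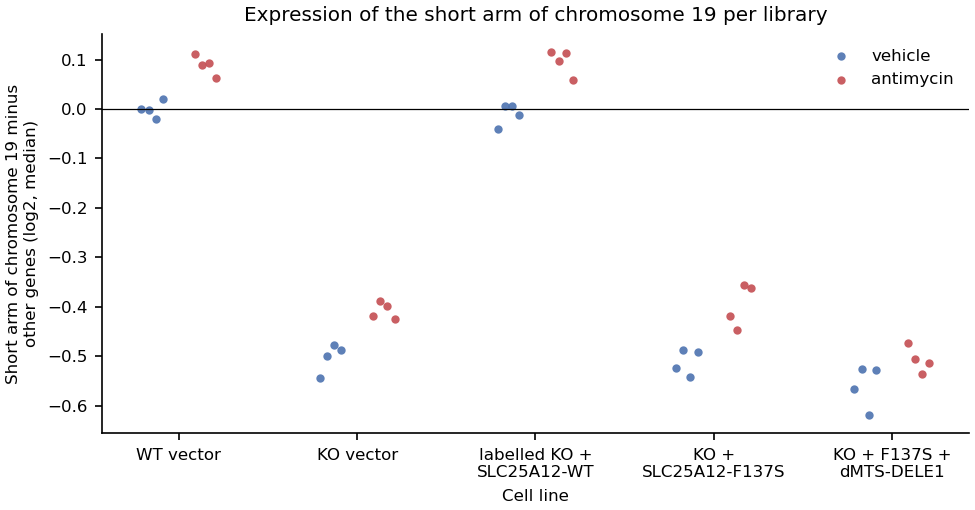
Median log2 expression of genes on the short arm of chromosome 19 minus that of other genes, relative to WT-vector cells in vehicle, 1 point per library, by cell line, with vehicle in blue and antimycin in red.

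Under antimycin, KO-vector cells stood below WT-vector cells in ISR genes. SLC25A12 was lower (-3.47 ± 0.05, adjusted p = 3.8e-61), as were NUPR1 (-1.36 ± 0.15), CHAC1 (-1.14 ± 0.10, adjusted p = 2.6e-14) and ADM2 (-1.05 ± 0.16). GDF15, which lies on the short arm of chromosome 19, was lower too (-2.78 ± 0.46, few counts). In the ISR list of 35 genes, 25 were lower, 5 higher and 5 did not pass (5 up and 26 down adjusted over the list alone, median -0.30, camera adjusted p = 2.7e-07). Serine and one-carbon genes (14 lower, 3 higher of 23, 4 up and 14 down adjusted over the list alone, camera adjusted p = 1.8e-04), tRNA synthetases (14 lower, 2 higher of 20, 2 up and 14 down adjusted over the list alone, camera adjusted p = 3.0e-07) and amino acid transporters (12 lower, 3 higher of 20, 3 up and 12 down adjusted over the list alone, camera adjusted p = 3.0e-04) were lower with them. PCK2 stood at -0.57 ± 0.04 and SLC6A9 at -1.01 ± 0.06. The mean log2 level of the ISR list was 0.36 lower (exact permutation p = 0.0286). HAS2 (-5.33 ± 0.25), DDR2 (-3.84 ± 0.08) and CASP8 (-2.52 ± 0.08) were lower and KIF1A (2.26 ± 0.04), MKRN3 (2.43 ± 0.13), TPTE (2.53 ± 0.13) and DBIL5P (6.24 ± 0.07) higher, among 8034 genes, 3938 higher and 4096 lower, 601 by at least 2-fold.

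The libraries labelled KO plus SLC25A12-WT stood close to WT-vector cells. SLC25A12 was higher than in KO-vector cells (3.65 ± 0.05, adjusted p = 3.9e-64) and against WT-vector cells its difference did not pass (0.01 ± 0.03, adjusted p = 1.0). Against KO-vector cells in vehicle, HAS2 (4.86 ± 0.21), CASP8 (2.87 ± 0.08) and DDR2 (2.60 ± 0.07) were higher and DBIL5P (-6.98 ± 0.06), TPTE (-2.48 ± 0.13), KIF1A (-2.28 ± 0.04) and FGF13 (-2.03 ± 0.08) lower, the reverse of KO-vector against WT-vector cells. SLC25A13 (0.15 ± 0.03), OMA1 (0.33 ± 0.04) and DELE1 (0.11 ± 0.04) were slightly higher. Of 8080 genes changed between KO-vector and WT-vector cells, 7040 changed the other way here, with 1938 expected from independent calls. The comparisons share the KO-vector libraries, but with these split between them the correlation across 12752 genes was still -0.882. Counts were 8004 genes in vehicle (47.8%, 4227 higher, 3777 lower, 568 by at least 2-fold) and 8076 under antimycin (48.2%, 4136 higher, 3940 lower, 592 by at least 2-fold).

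Against WT-vector cells directly, a comparison added after seeing the data, edgeR called 0 genes in vehicle (778 at an unadjusted p < 0.05, 4.65% of those tested, and 0 by DESeq2). Under antimycin it called 1, the cilium gene CFAP44, named after its value was seen (805 at an unadjusted p < 0.05, 1 by DESeq2), and for the difference in response 0 (756 at an unadjusted p < 0.05, 0 by DESeq2). F137S cells differed from WT-vector cells in 8226 genes in vehicle. These libraries are therefore not taken here as a rescue of the knockout. In these libraries antimycin raised CHAC1 (3.38 ± 0.12, adjusted p = 2.9e-31), ATF3 (1.60 ± 0.04), ASNS (1.61 ± 0.14), DDIT3 (0.88 ± 0.07), TRIB3 (0.41 ± 0.05) and ATF4 (0.36 ± 0.02, adjusted p = 2.7e-30), while GDF15 did not pass (0.94 ± 0.44, adjusted p = 0.069). BAIAP3 (1.92 ± 0.11), EPS8L2 (1.80 ± 0.16) and ZNNT1 (1.76 ± 0.14) rose, and GNG13 (-1.62 ± 0.11), LNP1 (-1.58 ± 0.11) and the small nucleolar RNA SNORD78 (-1.63 ± 0.16) fell. The ISR list had 29 of 35 genes up and 2 down (30 up and 3 down adjusted over the list alone, camera adjusted p = 2.5e-13), among 8760 genes, 4340 up and 4420 down, 546 by at least 2-fold. Their list level rose by 0.64 (exact permutation p = 0.0286).

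Under antimycin the labelled cells stood above KO-vector cells in SLC25A12 (3.44 ± 0.05, adjusted p = 1.0e-60), HAS2 (5.47 ± 0.24), DDR2 (3.79 ± 0.08) and NAPRT (3.00 ± 0.48, variable counts) and below them in MKRN3 (-2.53 ± 0.13), TPTE (-2.50 ± 0.13), KIF1A (-2.20 ± 0.04) and DBIL5P (-6.26 ± 0.07). Their response was more positive than that of KO-vector cells in CHAC1 (1.47 ± 0.18, adjusted p = 8.4e-08), DDR2 (1.19 ± 0.10), BAIAP3 (0.86 ± 0.15), ATF4 (0.29 ± 0.02, adjusted p = 9.5e-15), ATF3 (0.24 ± 0.06, adjusted p = 0.014) and TRIB3 (0.33 ± 0.07, adjusted p = 0.0021). DDIT3 (0.25 ± 0.09, adjusted p = 0.21), ASNS (0.66 ± 0.20, adjusted p = 0.078) and the scarce GDF15 did not pass. The labelled response was more negative in RASSF7 (-0.77 ± 0.20), RGS20 (-0.73 ± 0.21), SLC39A7 (-1.22 ± 0.33, variable counts) and the antisense RNA PSMG3-AS1 (-0.69 ± 0.14). In the ISR list, 16 of 35 genes had a more positive and 0 a more negative response (23 up and 1 down adjusted over the list alone, camera adjusted p = 3.6e-26), among 276 genes (118 more positive, 158 more negative, 15 by at least 2-fold). Without KO-vector antimycin replicate 1 the count was 180. The ISR list level rose by 0.27 more in the labelled cells but did not pass the planned permutation (p = 0.0543). With line means removed first, a permutation chosen after seeing the data, p = 0.000408. The share with a more positive response was 42.8% and became 57.3% with DESeq2 size factors.

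F137S cells, with SLC25A12 far above the native level, remained close to KO-vector cells. In vehicle SLC25A12 was 600-fold higher (9.23 ± 0.03, adjusted p = 2.4e-100), and HSPA6, an inducible heat shock chaperone, was higher (4.05 ± 0.20). Genes of the ISR were among the other genes called, with INHBE (1.23 ± 0.19), NUPR1 (1.03 ± 0.19, adjusted p = 0.0059), the lipoprotein receptor VLDLR (0.40 ± 0.09, adjusted p = 0.049), CTH (0.19 ± 0.04, adjusted p = 0.028), STC2 (0.15 ± 0.03, adjusted p = 0.0035) and CEBPG (0.13 ± 0.03, adjusted p = 0.028). The glutamine transporter SLC38A2 (0.13 ± 0.02, adjusted p = 0.0045), AMH (0.32 ± 0.06, adjusted p = 0.025), RERE (0.17 ± 0.04, adjusted p = 0.011), ZNNT1 (0.71 ± 0.16, adjusted p = 0.034) and SLC39A7 (1.16 ± 0.23, adjusted p = 0.037, variable counts) were also higher. SLC25A13 (-0.02 ± 0.03, adjusted p = 0.97), DELE1 (-0.00 ± 0.04, adjusted p = 1), EIF2AK1 (0.00 ± 0.02, adjusted p = 0.99) and OMA1 (0.05 ± 0.04, adjusted p = 0.93) did not pass. The ISR list leaned upward, 6 higher and 0 lower of 35 (20 up and 0 down adjusted over the list alone, median 0.12, camera adjusted p = 3.8e-16), and its mean log2 level was 0.21 higher (exact permutation p = 0.0286). p53 targets had 0 genes called higher of 20 (5 up and 0 down adjusted over the list alone, camera adjusted p = 4.7e-06) and amino acid transporters 1 (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.0019). edgeR called 14 genes, all higher, 6 by at least 2-fold, and DESeq2 27, 24 higher and 3 lower. The count was 5 without F137S replicate 4, 6 without KO-vector replicate 2, 8 without F137S replicate 1 and 6 with counts halved. Of 8080 genes that differed between KO-vector and WT-vector cells, 8 changed the other way in F137S cells (3.58 expected from independent calls). SLC25A12 itself is among them through the introduced construct. The count fell to between 2 and 5 without any 1 of 7 of the 12 libraries left out in turn. With the shared KO-vector libraries split, the correlation across genes was -0.0311.

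Under antimycin SLC25A12 (9.43 ± 0.03, adjusted p = 1.2e-100) and HSPA6 (3.20 ± 0.18) were higher in F137S than in KO-vector cells. INHBE, NUPR1, VLDLR, STC2 and CEBPG, called in vehicle, did not pass here (adjusted p = 0.385, 0.172, 0.972, 0.169 and 0.659). GDF15 (2.90 ± 0.45, few counts) was higher. NIBAN1 (0.33 ± 0.07, adjusted p = 0.0061), CTH (0.26 ± 0.04), SLC7A11 (0.20 ± 0.03) and the serine enzyme PSAT1 (0.08 ± 0.02, adjusted p = 0.021) were slightly higher, with AMH (0.52 ± 0.06), GNG13 (0.52 ± 0.11, adjusted p = 0.021) and the antisense RNA CCDC183-AS1 (0.60 ± 0.12, adjusted p = 0.0082). In the ISR list, 5 of 35 genes were higher and 0 lower (18 up and 0 down adjusted over the list alone, camera adjusted p = 8.4e-20), and of 20 amino acid transporters 1 was higher (5 up and 0 down adjusted over the list alone, camera adjusted p = 3.4e-04). The ISR list level was 0.21 higher (exact permutation p = 0.0286). edgeR called 19 genes, all higher, 5 by at least 2-fold, and DESeq2 33. Without KO-vector replicate 1 the count was 12.

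Antimycin raised ISR genes in F137S cells by about as much as in KO-vector cells. CHAC1 (1.70 ± 0.12, adjusted p = 7.4e-19), ATF3 (1.26 ± 0.04), ASNS (1.24 ± 0.15), DDIT3 (0.67 ± 0.07), GDF15 (1.53 ± 0.37), TRIB3 (0.23 ± 0.05) and ATF4 (0.07 ± 0.02, adjusted p = 1.8e-04) rose. Among the 35 ISR genes, 25 rose and 3 fell (25 up and 3 down adjusted over the list alone, median 0.25, camera adjusted p = 1.1e-05), and the list level rose by 0.37 (exact permutation p = 0.0286). TLCD1 (1.59 ± 0.07) and GUCA1B (1.47 ± 0.16) rose, CYP27B1 (-1.43 ± 0.08) and SNORA73B (-1.72 ± 0.14) fell, and DECR2 (1.39 ± 0.56, adjusted p = 0.037) and NDE1 (-1.72 ± 0.67, adjusted p = 0.032) moved with counts that jump between libraries. In all 8574 genes changed (51.2%), 4409 up and 4165 down, 469 by at least 2-fold. Against KO-vector cells no gene differed in response by edgeR (0 called, 711 at an unadjusted p < 0.05, 0 by DESeq2, 1 where the fit held only the groups compared, FAM83H, and 1 without the labelled libraries, SLC39A7, both named after their values were seen). ATF4 (0.00 ± 0.02, adjusted p = 1), ATF3 (-0.10 ± 0.06, adjusted p = 1), DDIT3 (0.04 ± 0.09, adjusted p = 1), TRIB3 (0.15 ± 0.07, adjusted p = 1), ASNS (0.29 ± 0.21, adjusted p = 1) and the scarce GDF15 did not pass. The ISR list had 0 genes higher and 0 lower of 35 (0 up and 0 down adjusted over the list alone, camera adjusted p = 0.9), and its level differed in response by -0.005 (exact permutation p = 0.963).

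F137S cells were also compared with the libraries labelled KO plus SLC25A12-WT. In vehicle SLC25A12 (5.57 ± 0.02, adjusted p = 6.5e-95), DBIL5P (6.96 ± 0.06), TPTE (2.53 ± 0.12) and KIF1A (2.26 ± 0.04) were higher and HAS2 (-4.78 ± 0.20), ZNF208 (-2.91 ± 0.19), CASP8 (-2.86 ± 0.08) and AGAP11 (-2.56 ± 0.14) lower, among 8183 genes (3888 higher, 4295 lower, 580 by at least 2-fold). Under antimycin SLC25A12 (5.99 ± 0.03), HSPA6 (2.56 ± 0.17), TPTE (2.56 ± 0.13) and DBIL5P (6.31 ± 0.07) were higher and HAS2 (-5.24 ± 0.24), DDR2 (-3.82 ± 0.08), DPYSL3 (-2.59 ± 0.18) and NAPRT (-3.26 ± 0.50, variable counts) lower, among 8202 genes (4008 higher, 4194 lower, 590 by at least 2-fold). The response of F137S cells was more negative in CHAC1 (-1.68 ± 0.17, adjusted p = 3.8e-10), ATF4 (-0.28 ± 0.02, adjusted p = 1.4e-14), ATF3 (-0.34 ± 0.06), DDR2 (-1.31 ± 0.10), NAPRT (-2.89 ± 0.69, adjusted p = 0.025, variable counts) and the pseudogene ASNSP1 (-0.92 ± 0.23, adjusted p = 0.021). It was more positive in SLC25A12 (0.42 ± 0.04, adjusted p = 1.7e-14), which fell in the labelled libraries and did not pass in F137S cells, and in CACNA1B (0.91 ± 0.23, adjusted p = 0.02), NANOS1 (0.62 ± 0.14, adjusted p = 0.0081), BCDIN3D (0.55 ± 0.13, adjusted p = 0.01) and the antisense RNA PSMG3-AS1 (0.62 ± 0.14). DDIT3 (-0.21 ± 0.09, adjusted p = 0.34), TRIB3 (-0.18 ± 0.07, adjusted p = 0.25), ASNS (-0.37 ± 0.20, adjusted p = 0.52) and GDF15 (0.59 ± 0.61, adjusted p = 0.8) did not pass. Among the 35 ISR genes, 16 had a more negative and 0 a more positive response (1 up and 24 down adjusted over the list alone, camera adjusted p = 6.1e-29), among 215 genes (108 more positive, 107 more negative, 10 by at least 2-fold). The share with a more positive response was 50.2% and became 40.2% with DESeq2 size factors. The list level rose by 0.27 less (permutation p = 0.000408). This planned permutation also depends on the standing difference between the lines, which here changed sign between treatments. The level was 0.11 higher in vehicle and 0.16 lower under antimycin in F137S cells (exact permutation p = 0.0286 each). The vehicle difference is opposite in sign to that of KO-vector minus WT-vector cells, -0.10, which did not pass (exact permutation p = 0.0571).

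dMTS-DELE1 cells had ISR genes high already in vehicle. Against F137S cells, DELE1 was 116-fold higher (6.86 ± 0.04, adjusted p = 2.4e-49) and SLC25A12 2.01-fold higher (1.00 ± 0.02, adjusted p = 1.5e-53). GDF15 (5.65 ± 0.27), INHBE (4.68 ± 0.12), NUPR1 (3.37 ± 0.14), KLHDC7B (7.49 ± 0.28) and the fucosyltransferase FUT1 (4.12 ± 0.16) were higher. HSPA6 (-0.90 ± 0.15), the glucose transporter SLC2A4 (-0.85 ± 0.13), ATP2A3 (-0.77 ± 0.13) and APBA2 (-0.79 ± 0.28, adjusted p = 0.025) were lower. Of 35 ISR genes, 31 were higher, 1 lower and 3 did not pass (31 up and 1 down adjusted over the list alone, median 0.77, camera adjusted p = 1.2e-39). The mean log2 level of the list was 5.52 ± 0.0502 against 4.22 ± 0.0409, a difference of 1.30 (exact permutation p = 0.0286), above the level that antimycin reached in WT-vector cells. Of 20 amino acid transporters, 11 were higher and 6 lower (11 up and 6 down adjusted over the list alone, camera adjusted p = 8.3e-06), with SLC6A9 (1.16 ± 0.06) and SLC7A3 (1.16 ± 0.08). tRNA synthetases were 13 higher and 4 lower of 20 (13 up and 4 down adjusted over the list alone, camera adjusted p = 7.7e-07), with WARS1 (0.61 ± 0.02) and CARS1 (0.81 ± 0.27), and the one-carbon enzyme ALDH1L2 was higher (0.87 ± 0.03).

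Energy, sterol and proliferation genes were lower in dMTS-DELE1 cells. Of 25 cholesterol synthesis genes, 19 were lower and 0 higher (0 up and 19 down adjusted over the list alone, median -0.26, camera adjusted p = 2.7e-11). An example is INSIG1 (-0.43 ± 0.03). Of 22 genes of the tricarboxylic acid cycle, 17 were lower and 0 higher (0 up and 18 down adjusted over the list alone, camera adjusted p = 1.7e-06), with IDH3G at -0.30 ± 0.04. Nuclear genes of complexes II to V were 31 lower and 0 higher of 36 (0 up and 32 down adjusted over the list alone, camera adjusted p = 4.7e-10, but adjusted p = 0.054 with an estimated correlation). Complex I genes were 25 lower and 1 higher of 37 (1 up and 26 down adjusted over the list alone, camera adjusted p = 4.8e-05, but adjusted p = 0.16 with an estimated correlation). Mitochondrial ribosomal protein genes were 45 lower and 1 higher of 74 (2 up and 47 down adjusted over the list alone, camera adjusted p = 1.7e-06, but adjusted p = 0.074 with an estimated correlation). Of 35 cell cycle genes, 29 were lower and 2 higher (2 up and 29 down adjusted over the list alone, camera adjusted p = 2.9e-09). The p53 targets were 15 higher and 3 lower of 20 (15 up and 3 down adjusted over the list alone, camera adjusted p = 5.4e-10), with CDKN1A (1.39 ± 0.07) and SPATA18 (1.31 ± 0.09). Heat shock genes were 14 lower and 0 higher of 19 (0 up and 14 down adjusted over the list alone, camera adjusted p = 1.7e-06). Endoplasmic reticulum genes leaned upward (11 higher, 6 lower of 24, 11 up and 6 down adjusted over the list alone, camera adjusted p = 0.011, but adjusted p = 0.12 with an estimated correlation), with XBP1 (0.75 ± 0.02), and the growth factor VEGFA was higher (0.74 ± 0.04). The count was 6995 genes (41.8%), 2963 higher and 4032 lower, with 344 higher and 32 lower among those of at least 2-fold (376).

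Under antimycin SLC25A12 (1.16 ± 0.02, adjusted p = 2.9e-57), DELE1 (6.90 ± 0.03, adjusted p = 1.5e-49), KLHDC7B (6.90 ± 0.26), INHBE (4.50 ± 0.12), GDF15 (4.22 ± 0.22) and NUPR1 (2.90 ± 0.14) were higher and HSPA6 (-1.31 ± 0.15) lower in dMTS-DELE1 than in F137S cells. RGL2 (-2.19 ± 0.48), PYCR3 (-1.87 ± 0.64, adjusted p = 0.014) and FAM189B (-1.20 ± 0.41, adjusted p = 0.014) were lower with counts that jump between libraries. As many as 31 of 35 ISR genes were higher and 2 lower (31 up and 2 down adjusted over the list alone, camera adjusted p = 3.8e-25), and the list level was 1.12 higher (exact permutation p = 0.0286). Of 25 cholesterol genes 20 were lower and 0 higher (0 up and 20 down adjusted over the list alone, camera adjusted p = 4.9e-10). Of 22 tricarboxylic acid cycle genes 18 were lower and 1 higher (1 up and 18 down adjusted over the list alone, camera adjusted p = 4.9e-06), and of 36 genes of complexes II to V 34 lower and 0 higher (0 up and 34 down adjusted over the list alone, camera adjusted p = 1.9e-10). p53 targets were 15 higher and 3 lower of 20 (15 up and 3 down adjusted over the list alone, camera adjusted p = 9.3e-07). The count was 9086 genes (54.3%), 4262 higher and 4824 lower, 494 by at least 2-fold.

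Fewer genes changed under antimycin in dMTS-DELE1 cells. ATF3 (0.99 ± 0.04), ASNS (0.79 ± 0.14), DDIT3 (0.40 ± 0.06), CHAC1 (0.40 ± 0.10, adjusted p = 7.8e-04), TRIB3 (0.17 ± 0.04) and ATF4 (0.09 ± 0.02, adjusted p = 1.0e-05) still rose, while GDF15 did not pass (0.11 ± 0.17, adjusted p = 0.68). DELE1 counts, which come almost wholly from the introduced construct in these cells, rose slightly (0.19 ± 0.03, adjusted p = 2.6e-07). They do not measure the native DELE1 gene. Within the ISR list, 22 of 35 genes rose and 3 fell (23 up and 3 down adjusted over the list alone, median 0.17, camera adjusted p = 6.8e-09), and the list level rose by 0.20 (exact permutation p = 0.0286). Endoplasmic reticulum genes rose, 18 up and 0 down of 24 (19 up and 0 down adjusted over the list alone, camera adjusted p = 4.7e-09). The p53 targets were 12 up and 0 down of 20 (12 up and 1 down adjusted over the list alone, camera adjusted p = 3.8e-04), and heat shock genes 14 down and 0 up of 19 (0 up and 15 down adjusted over the list alone, camera adjusted p = 5.6e-09). DUSP8 (1.30 ± 0.33), TLCD1 (1.11 ± 0.08), ZNNT1 (1.09 ± 0.13) and SOX30 (1.04 ± 0.21) rose and TXNIP, a brake on glucose uptake (-1.28 ± 0.05), SNORA73B (-1.71 ± 0.15) and FAM189B (-1.29 ± 0.41, jumping counts) fell. In all 5847 genes changed (34.9%), 2945 up and 2902 down, 171 by at least 2-fold, and the spread of log2 fold changes was 0.662 times that in WT-vector cells.

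Compared directly with F137S cells, the response of dMTS-DELE1 cells was more negative in GDF15 (-1.43 ± 0.41, adjusted p = 0.013), CHAC1 (-1.30 ± 0.15, adjusted p = 5.4e-09), SLC6A9 (-0.67 ± 0.08), the stress sensor SESN2 (-0.60 ± 0.04), ATF3 (-0.27 ± 0.06) and DDIT3 (-0.27 ± 0.09, adjusted p = 0.031). ATF4 (0.02 ± 0.02, adjusted p = 0.73), TRIB3 (-0.06 ± 0.06, adjusted p = 0.61) and ASNS (-0.46 ± 0.20, adjusted p = 0.14) did not pass. The noncoding RNA MALAT1 (-0.94 ± 0.21) and the ion channel HCN4 (-0.91 ± 0.24, adjusted p = 0.0047) had a more negative response. SOX6 (1.04 ± 0.17), ZBTB20 (0.91 ± 0.18) and PLCL1 (0.80 ± 0.22, adjusted p = 0.0082), which fell in F137S cells, had a more positive one. Within the ISR list, 10 of 35 genes were more negative and 3 more positive (4 up and 13 down adjusted over the list alone, camera adjusted p = 0.0037), and of 23 serine and one-carbon genes 6 were more negative and 1 more positive (1 up and 8 down adjusted over the list alone, camera adjusted p = 0.012). Endoplasmic reticulum genes leaned to a more positive response, 8 more positive and 2 more negative of 24 (9 up and 3 down adjusted over the list alone, camera adjusted p = 0.012, but adjusted p = 0.18 with an estimated correlation), with DNAJB9 (0.58 ± 0.07) and SEC24D (0.40 ± 0.05). So did cell cycle genes, 12 more positive and 3 more negative of 35 (13 up and 3 down adjusted over the list alone, camera adjusted p = 0.012, but adjusted p = 0.13 with an estimated correlation), with BUB1B (0.26 ± 0.04), AURKA (0.23 ± 0.04) and CCNA2 (0.23 ± 0.04), which fell in both lines and by less in dMTS-DELE1 cells. The count was 1998 genes (11.9%), 1379 more positive and 619 more negative, 36 by at least 2-fold. The ISR list level rose by 0.18 less (planned permutation p = 0.632, and 0.00286 with the line means removed first, a test chosen after seeing the data). The planned permutation counts the large standing difference between these lines as noise. The list calls above for which no estimated correlation is given kept an adjusted p < 0.05 with it.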

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

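The tests of line means removed first, of chromosome arms, of the labelled libraries against WT-vector cells and of genes that vary between libraries were chosen after the results were seen. Splits of the libraries were planned, but the bounds for these tests were written down after split counts had been seen.

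The antimycin response differed between lines in single genes, while the difference in ISR list level passed the planned permutation in 1 of the 4 comparisons below. That permutation counts the standing difference between the lines as noise, so its p depends on that difference too. The standing difference changed sign between treatments for F137S and labelled cells, and was large in both treatments for dMTS-DELE1 and F137S cells. The 4 outcomes therefore do not rank the differences of response. For KO-vector minus WT-vector cells, 262 genes differed in response and the level difference of -0.26 did not pass (permutation p = 0.0633). For the libraries labelled KO plus SLC25A12-WT minus KO-vector cells, 276 genes differed (180 without KO-vector antimycin replicate 1) and the level difference of 0.27 did not pass (permutation p = 0.0543). For F137S cells minus those libraries, 215 genes differed and the level difference of -0.27 passed (permutation p = 0.000408). For dMTS-DELE1 minus F137S cells, 1998 genes differed and the level difference of -0.18 did not pass (permutation p = 0.632). With line means removed first, all 4 passed (permutation p = 0.000408, 0.000408, 0.000408 and 0.00286).

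Other splits of the same libraries, refitted on those libraries alone, tested whether chance alone could give as many calls (each bracket gives the real count, then the highest of the other splits). Of 35 splits per pair of groups, only the real one gave as many genes for the antimycin responses. That is 1 in 35, the smallest share these splits can give, and many comparisons were made. It argues against a chance split of the libraries but does not test differences between cultures. This held in WT-vector (8700, 1), KO-vector (8604, 1), labelled KO plus SLC25A12-WT (8755, 0), F137S (8199, 2) and dMTS-DELE1 cells (5325, 2). The same held between lines in vehicle for KO-vector against WT-vector (8091, 1), the labelled libraries against KO-vector (7941, 1), F137S against the labelled libraries (8140, 1) and dMTS-DELE1 against F137S (6387, 1). Under antimycin it held for the same pairs (8056, 2 and 8163, 0 and 7880, 1 and 8696, 0). It also held in vehicle for F137S against WT-vector (8274, 0) and, by the smallest margin, under antimycin for F137S against KO-vector (14, 3). Chance cannot be excluded for F137S against KO-vector in vehicle (11 genes, 12 in another split, 2 of 35 splits as many). Nor can it for the labelled libraries against WT-vector in vehicle (1, 5, 23 of 35 splits) and under antimycin (0, 6, 35 of 35).

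For the differences of response, 100 splits were drawn, and the counts below include the real split. For F137S minus KO-vector, 16 splits gave as many genes (1 real, 13 in another), and chance cannot be excluded. For KO-vector minus WT-vector 2 did so (312 genes, 6624 in another), for the labelled libraries minus KO-vector 3 (313, 6591), for F137S minus the labelled libraries 2 (199, 6470) and for dMTS-DELE1 minus F137S 3 (1513, 5283). In these 4 the splits do not test chance. They mix lines that themselves differ in many genes, which adds to the spread, and the median of the other splits was 0. Those with many times the real count point to the structure of the samples.

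SLC25A12 in the libraries labelled KO plus SLC25A12-WT stood at the level of WT-vector cells, and 4.65% of genes had an unadjusted p < 0.05 between them in vehicle, about the share expected without any difference. This is what a line without the knockout, by a wrong label or a mix-up of cultures, would give. A re-expressed SLC25A12 that returned the knockout line to its parental state could also do so only if it undid the deficit of the short arm of chromosome 19, which was -0.00972 in these libraries. Whether that arm can depend on SLC25A12 is not known from these data, which keeps the second explanation open. Until the label is checked at the DNA, these libraries do not show what SLC25A12-WT does in knockout cells.

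Genes of the short arm of chromosome 19 were lower in KO-vector cells, with a median of -0.51. Fewer copies of this arm in the knockout line would give such a block, which ends at the long arm. GC content and gene length are argued against, since the median was -0.500 after their trends were removed. A loss of the arm's expression through the missing SLC25A12 cannot be told apart from a copy loss, since F137S cells showed -0.512 but express a mutant protein. With 1 knockout line, differences between KO-vector and WT-vector cells may stem from the knockout or from the line.

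A set of 71 genes, among them RPS9, PYCR3 and NDE1, jumped between libraries of a group (pooled SD of at least 0.5, against a median of 0.0621). They made up 26.7% of the tested genes of the major histocompatibility complex and 0.540% elsewhere (Fisher exact p = 6.5e-12), and 42 of 67 lay within 1e6 bases of another, with at most 20 in random draws. Reads shared between alternate copies of such regions are a candidate explanation. Counting noise is argued against, since it gives an SD of 0.164 at the lowest mean count among them (157). No biological explanation was tested.

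In 4 of 60 tests, 1 per group and measure, 1 library stood apart from the other 3 by Dixon's ratio, where chance alone gives about 1 in 20, or 3. SLC25A12 reached 3.43 CPM in KO-vector vehicle replicate 1 (others 2.96 to 2.99) and DELE1 46.4 CPM in replicate 3 (others at most 46.0). Library totals, in units of 1e6, were 31.7 in KO-vector vehicle replicate 1 (others at least 31.9) and 30.8 in F137S antimycin replicate 3 (others 31.8 to 31.9).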

How the results depend on the processing

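Tests with counts halved, without the labelled libraries, with line means removed first and without the short arm of chromosome 19 were chosen after the results were seen. Of 387 named-gene results, 331 kept direction and side of the threshold under all alternatives. Changes in the others were mostly lost calls. Calling only genes of at least 2-fold left, for the antimycin responses, 595 genes in WT-vector, 483 in KO-vector, 546 in labelled KO plus SLC25A12-WT, 469 in F137S and 171 in dMTS-DELE1 cells. It left 572, 568, 6, 580 and 376 for the vehicle comparisons (KO-vector against WT-vector, labelled against KO-vector, F137S against KO-vector, F137S against labelled, dMTS-DELE1 against F137S) and 601, 592, 5, 590 and 494 for the same under antimycin. For the differences of response it left 15 (KO-vector minus WT-vector), 15 (labelled minus KO-vector), 10 (F137S minus labelled) and 36 (dMTS-DELE1 minus F137S), all by the stricter rule itself. The small counts of F137S against KO-vector moved as well. In vehicle, 14 genes became 6 with counts halved, 27 with DESeq2 and 5 to 11 with each library left out (5 without F137S replicate 4, 6 without KO-vector replicate 2, 8 without F137S replicate 1). Under antimycin, 19 became 33 with DESeq2 and 12 to 28 with each library left out (12 without KO-vector replicate 1). The differences between KO-vector and WT-vector cells that were reversed in F137S cells, 8 in number, became 3 with counts halved. They became 5 with the compared groups alone and 2 to 8 with each library left out. The 276 genes of labelled minus KO-vector became 180 to 247 (180 without KO-vector antimycin replicate 1). The 0 genes of F137S minus KO-vector (711 at an unadjusted p < 0.05 by edgeR, 0 by DESeq2) became 1 with the compared groups alone and 1 without the labelled libraries. The cause was not tested.

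For the ISR list level, KO-vector minus WT-vector in vehicle passed as -0.12 without members of other lists and as -0.10 with the replicate block (exact permutation p = 0.0286 each), not with size factors, a prior count of 0.5 or counts halved (exact permutation p = 0.0571 each), and ranged from -0.124 to -0.0863 with each library left out, passing only as -0.124 without KO-vector replicate 3 (exact permutation p = 0.0286, the others 0.0571 or 0.0857). The level of labelled minus KO-vector ranged from 0.0821 to 0.12 and of F137S minus labelled from 0.10 to 0.13, each losing its call (exact permutation p = 0.0571) when any of the 4 labelled vehicle libraries was left out. The difference of response between KO-vector and WT-vector passed as -0.27 with DESeq2 size factors (permutation p = 0.0498), -0.27 with counts halved (permutation p = 0.0343) and -0.26 with line means removed first. It did not pass as -0.22 with a prior count of 0.5 (permutation p = 0.181), -0.24 without members of other lists (permutation p = 0.098) or -0.26 with the replicate block (permutation p = 0.0527). With each library left out it ranged from -0.27 to -0.23 (permutation p from 0.0449 to 0.115). That of labelled minus KO-vector passed as 0.28 with size factors, 0.27 with the replicate block, 0.28 with counts halved and 0.27 with line means removed first. It did not pass as 0.23 with a prior count of 0.5 (permutation p = 0.179) or 0.25 without members of other lists (permutation p = 0.0886). With each library left out it ranged from 0.24 to 0.28 (permutation p from 0.038 to 0.104). That of dMTS-DELE1 minus F137S passed as -0.18 with line means removed first. That of F137S minus KO-vector turned to 0.0037 with counts halved and ranged from -0.0271 to 0.0115. Values close to 0 changed sign. These were EIF2AK1 in KO-vector against WT-vector (0.0061 without a filter, 0.00545 without the labelled libraries, -0.0227 to 0.00121 with each library left out) and in F137S against KO-vector (-0.0105 to 0.0164), and DELE1 there (-0.0272 to 0.0256). In the differences of response they were ATF4 in F137S minus KO-vector (-0.0106 to 0.0217), DDIT3 there (-0.0373 to 0.0993), ATF4 in dMTS-DELE1 minus F137S (-0.00137 with the compared groups alone, -0.0105 to 0.0266) and GDF15 in KO-vector minus WT-vector (-0.0176 with counts halved, -0.751 to 2.61 on few counts). None of these genes passed. Apart from the ISR level, the replicate block moved no count by over 1.5 times. All alternatives fixed before were run.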

Other observations

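The tests of HOX clusters and of other chromosome arms were chosen after the results were seen.

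Most tested HOXA genes, which set position along the body axis, fell under antimycin in the lines given below. Whether they fell more than other genes was not tested, and 4415 of all 16739 genes fell in WT-vector cells. In WT-vector cells 11 of 11 tested HOXA genes fell (median -0.50), among them HOXA11 (-1.15 ± 0.05), HOXA2 (-1.02 ± 0.17) and HOXA13 (-0.75 ± 0.05). In KO-vector cells 11 of 11 fell (median -0.37), with HOXA11 at -1.10 ± 0.05, HOXA2 at -0.69 ± 0.16 and HOXA13 at -0.36 ± 0.05. In F137S cells 9 of 11 fell (median -0.38) and in dMTS-DELE1 cells 8 of 11 (median -0.41). Of 9 tested HOXB genes, 5 fell and 2 rose in WT-vector cells. Of 9 HOXC genes 2 fell and 1 rose, and of 9 HOXD genes 1 fell and 2 rose.

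Some hypoxia, interferon and antioxidant genes also differed between KO-vector and WT-vector cells in vehicle, without a list call that holds under the estimated correlation. Of 33 hypoxia and glycolysis genes, 18 were lower and 3 higher (3 up and 19 down adjusted over the list alone, camera adjusted p = 0.0058, but adjusted p = 0.1 with an estimated correlation), with ALDOC (-1.24 ± 0.09) and BHLHE40 (-0.76 ± 0.07). Of 26 interferon response genes, 12 were higher and 3 lower (13 up and 3 down adjusted over the list alone, camera adjusted p = 0.016, but adjusted p = 0.055 with an estimated correlation), with IFI44L (1.19 ± 0.14) and IFI6 (0.84 ± 0.09). The antioxidant genes NQO1 (0.96 ± 0.04) and HMOX1 (0.72 ± 0.04) were higher, while the NRF2 target list had no common direction (8 higher, 5 lower of 19, 8 up and 5 down adjusted over the list alone, camera adjusted p = 0.16). In dMTS-DELE1 against F137S cells in vehicle, 19 hypoxia genes were lower and 4 higher of 33 (4 up and 19 down adjusted over the list alone, camera adjusted p = 5.8e-05, adjusted p = 0.021 with an estimated correlation).

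Beside the short arm of chromosome 19, the medians in KO-vector against WT-vector cells were -0.19 over 208 genes of the short arm of chromosome 17, -0.10 over 316 of 16p and 0.11 over 742 of 1p.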
